A study of Homo sapiens with 2 samples.

How the data were processed

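RNA was measured in the 2 channels of 1 array: total RNA of vehicle-treated MOLT4 cells carried the Cy3 dye and total RNA of LSD1 inhibitor-treated MOLT4 cells carried the Cy5 dye, per the labels. The dyes were not swapped on a second array used here, so treatment and dye are the same contrast. Per the labels' protocols, RNA was extracted with Trizol, reverse transcribed from a T7 primer and transcribed with labelled nucleotide. Agilent Feature Extraction 10.7.3.1 is named in the submitters' processing notes. The background correction, the dye normalization and any later scaling are not given in the sources used here.

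The deposited table gives 1 linear intensity per feature (spot) and channel, for 62976 features numbered from 1 to 62976 without a gap. No value was missing and none was 0 or negative. The table used here pairs these numbers with no probe or gene, and the human gene table used here holds no feature numbers, so no feature was named by gene. The 37 gene lists (1039 symbols) fixed before the data were examined, among them NOTCH, TAL1 and LSD1 complex genes, were therefore not tested, and nothing is reported for them. Control spots and flags for signal above background were not used here, so all 62976 features entered the counts.

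Each intensity was put on the log2 scale, and the log2 difference was taken as LSD1 inhibitor minus vehicle. As also fixed beforehand, the median difference over all features was subtracted, features were kept when their mean log2 value over both channels was at or above that of the median feature (16.2 intensity units), and features at least 2-fold apart were counted. The plan was to count genes and to average the probes of a gene. Features were counted instead, so a transcript with several features counts several times. With 1 sample per group there is no replicate error, no test was run across samples and no p-value is given. The number of arrays limits the precision. The rule for naming items, also fixed beforehand, allowed 2 features that were higher and 2 that were lower when genes could not be named: those with the largest differences among the kept features.

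The alternatives fixed before the data were examined were no centring, loess of the difference on the mean log2 value (span 0.3), quantile normalization, no filter, a filter at the 70th percentile, an offset of 50 intensity units before log2, and thresholds of 1.5-fold and 3-fold. Alternatives chosen after seeing the data were a restriction to features above the floor band of both channels, a mean log2 value of at least 6 (64 intensity units), centring on features above the floor band, a loess curve fitted only to features above the floor band in both channels, leaving out groups of features with near-equal values, and subtracting the median of each block of 16 rows and 41 columns of the array. The floor band of a channel ran from its lowest log2 value to the mirror image of that value about the peak of the histogram (bins of 0.05). Groups of near-equal features were found among features with an intensity of at least 500 in either channel, on log2(intensity + 50): a feature needed at least 6 features, itself included, within 0.1 and at least 4 times the density of the surrounding ring, and linked sets of at least 5 were kept. Their spread is bounded by that search radius. The layout of 384 rows and 164 columns was inferred from the feature numbers: values of features in the floor band of both channels correlated across features 164 numbers apart (r = 0.52 in the vehicle channel) and anticorrelated at 82 numbers apart (r = -0.47). The correlation was as high at 328 numbers apart (r = 0.53), which is a multiple of 164, and the smaller spacing was taken, so positions rest on this choice.

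The steps were tested on data simulated for this comparison from the mean values of all 62976 features. The 200 changed features were planted only among those with a mean log2 value of at least 6. Of the features planted at a log2 change of 1.5, 94% were counted as higher, and of those planted at -1.5, 92% were counted as lower. All features planted at 3 or -3 were counted. Every simulated feature was shifted by the same amount, unlike the deposited values, so the effect of a median set by floor values was not tested. Calls at lower mean values and the rate of false calls were not tested either. The group search found each of the 4 planted groups, with at least 90% of the members of each. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.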

Results

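MOLT4 is an established human T-cell acute lymphoblastic leukemia line. LSD1, encoded by KDM1A, is a histone lysine demethylase that works within corepressor complexes. To ask how blocking this enzyme changes gene expression in the leukemia cells, cultures were given 12 μM of an LSD1 inhibitor, or 0.01% DMSO as the vehicle, for 24 h. Their RNA was hybridized together to 1 Agilent array, with the vehicle sample in Cy3 and the inhibitor sample in Cy5. Each group held 1 sample. All differences below therefore lack a replicate check and describe this pair of samples, and a difference between the dyes is not separable from a difference between the treatments. Items on the array are given by feature number, without gene names, so the levels of KDM1A itself and of any pathway were not analysed here.

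The 2 channels had similar ranges. The median intensity was 15.6 in the vehicle channel and 19.7 in the inhibitor channel, the 75th percentile was 268 and 270, and the 99th percentile was 39245 and 38652. Both channels piled up at a low floor. The floor band peaked at 9.03 intensity units in the vehicle channel and at 5.19 in the inhibitor channel, and it reached 13.2 and 7.39 units. It held 47.8% of features in the vehicle channel and 38.2% in the inhibitor channel. In both channels at once, 22567 features (35.8%) lay in the floor band, and their median log2 difference was -0.66. Another 7513 features lay in the floor band only in the vehicle channel and 1473 only in the inhibitor channel. The remaining 31423 features (49.9%) were above it in both, with a median log2 difference of -0.02 and an interquartile range of 0.54. Across these features, which are not independent replicates, the log2 intensities of the 2 channels correlated with Pearson's r = 0.983.

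**Figure D1:**
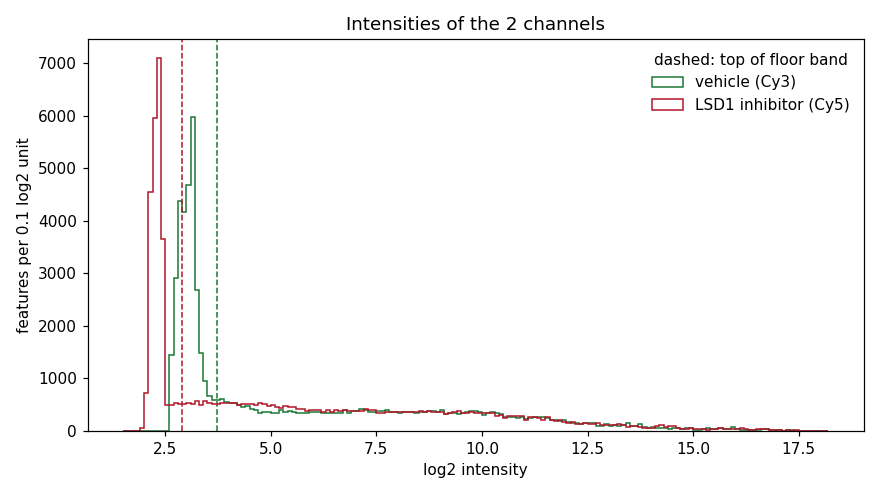
Histograms of log2 intensity (x axis) in features per 0.1 log2 unit (y axis) for the vehicle channel (Cy3) and the LSD1 inhibitor channel (Cy5) of 1 array, with dashed lines at the top of each floor band. The floor band of the inhibitor channel peaks lower (5.19 units) than that of the vehicle channel (9.03 units), while the upper parts of both curves overlap.

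More features were higher than lower in the inhibitor sample under the planned centring and filter. Of the 31488 features kept by the filter on mean value, 3351 (10.6%) were at least 2-fold higher in the inhibitor sample and 201 (0.638%) were at least 2-fold lower, so 94.3% of the features counted as 2-fold apart were higher. The size of this imbalance depended on the filter and on the scaling. With no filter, 5461 features were higher and 2161 lower (71.6% higher), and 3109 and 1885 of these had at least 1 channel in the floor band. The median log2 difference over all features was -0.28 before centring, and subtracting it raised every difference by that amount. Without centring, 2178 features were higher and 441 lower (83.2% higher). Loess gave 1717 and 746 (69.7% higher), and quantile normalization gave 1614 and 858 (65.3% higher). Of the 3351 higher features, 999 (29.8%) had at least 1 channel in the floor band, where a ratio is only a bound. Among features above the floor band in both channels, the 2-fold split turned with the scaling: 2352 were higher and 276 lower with the median subtracted, 1220 and 633 without centring, and 976 and 1228 after loess. A loess curve fitted only to these features gave 1306 higher and 456 lower. At 1.5-fold, fewer of these features were higher than lower after the loess over all features, 2761 against 3485. At 4-fold, more of them were higher than lower after that loess, 226 against 83.

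Well above the floor, higher features outnumbered lower ones under each scaling examined there, but by less at 1.5-fold. At a mean log2 value of at least 6, 1662 features were at least 1.5-fold higher and 1209 lower without centring. The 1.5-fold counts were 1746 and 1140 after loess, and 4258 and 291 with the median of all features subtracted. Among the 23413 features with a mean log2 value of at least 6, 594 were at least 2-fold higher and 136 at least 2-fold lower without centring, 611 and 128 after loess, and 1131 and 71 with the median of all features subtracted. At 4-fold, 208 features were higher and 36 lower without centring, 211 and 36 after loess, and 243 and 36 with the median subtracted. At 8-fold, 75, 77 and 91 features were higher under these scalings, and 0 were lower under each of them. Groups of features with nearly equal values held part of these: without them, the 8-fold counts were 38, 40 and 49 higher. The spread between features varied with intensity: the interquartile range of the log2 difference was 0.133 at mean log2 values from 2 to 3, where most features lay in the floor bands, 1.39 from 4 to 5, 0.579 from 6 to 7, 0.411 from 10 to 11 and 0.698 from 14 to 15. In the range from 4 to 5, 30.4% of features were at least 2-fold higher and 4.99% at least 2-fold lower without centring, against 1.14% and 0.138% from 10 to 11. The share of higher features was 11.5% from 14 to 15, and the share of lower features was 8.97% from 15 to 16. Of the 77 higher features from 14 to 15, 72 belonged to groups of nearly equal features, as did all 35 lower features from 15 to 16.

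**Figure D2:**
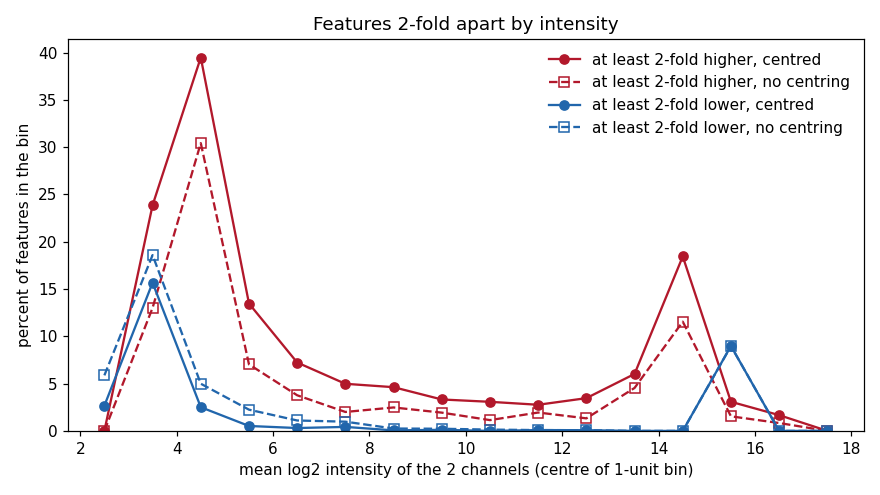
Percentage of features at least 2-fold higher or lower in the inhibitor sample (y axis) in bins of 1 unit of mean log2 intensity (x axis), with the median of all features subtracted (solid lines) and without centring (dashed lines), 1 array. The share of higher features is largest in the bin from 4 to 5, at 39.5% with centring and 30.4% without.

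The 10 largest increases ended at similar intensities in the inhibitor sample. Feature 38602 went from 36.1 units in the vehicle sample to 1722 in the inhibitor sample, a log2 difference of 5.85 after centring and 5.58 as deposited. Feature 61914 went from 33.9 to 1615 units, a log2 difference of 5.85 after centring and 5.57 as deposited. The 10 features with the largest differences all lay between 33.9 and 64.1 units in the vehicle sample and between 1577 and 1815 in the inhibitor sample. Whether they measure different transcripts or repeat 1 probe was not tested, so they may not be 10 separate increases. Their mean log2 difference as deposited was 5.28 ± 0.28 (SD across features of 1 array), which is 38.8-fold. The next feature in rank went from 11.04 units, inside the vehicle channel's floor band, to 265 units. On the inferred layout of the array the 10 features spanned rows 79 to 378 of 384, and their median nearest distance was as short or shorter in 0.67% of random sets of 10.

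The largest decreases ended in the floor band of the inhibitor channel. Feature 30355 was at 64.4 units in the vehicle sample and at 4.37 in the inhibitor sample, with a log2 difference of -3.61 after centring. Measured against the top of that floor band, its deposited value was at least 8.71-fold lower. Feature 51581 was at 53.4 and 7.27 units, with a log2 difference of -2.60 after centring, and was at least 7.22-fold lower by the same measure. With an offset of 50 units added before log2, the differences were -1.01 for feature 30355 and -0.79 for feature 51581, and the latter no longer passed the 2-fold threshold.

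Many of the brightest changed features shared their values with others. In all, 361 features fell into 13 groups whose members had nearly equal intensities in both channels, and these held 216 of the 3351 higher and 35 of the 201 lower features. Of these groups, 9 had between 35 and 39 features each. One group of 37 features went from a median of 9053 units to 105766, a log2 difference of 3.55 ± 0.03 (SD across features) as deposited. Another, of 35 features, went from 4338 to 20753 units (2.26 ± 0.03), a further set of 35 from 12218 to 49993 units (2.03 ± 0.03), and a set of 36 from 1342 to 3571 units (1.42 ± 0.04). In the opposite direction, 35 features went from a median of 108601 units to 19624, a log2 difference of -2.47 ± 0.04, and 2 of the other large groups lay lower by less than 2-fold, at -0.76 ± 0.03 (37 features) and -0.88 ± 0.03 (36 features). A group of 39 features had a log2 difference of 0.79 as deposited and 1.06 after centring, so that 37 of its members passed the 2-fold threshold only through the centring. Without the groups, 95 features with a mean log2 value of at least 6 were at least 4-fold higher and 1 was at least 4-fold lower, with no centring.

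**Figure D3:**
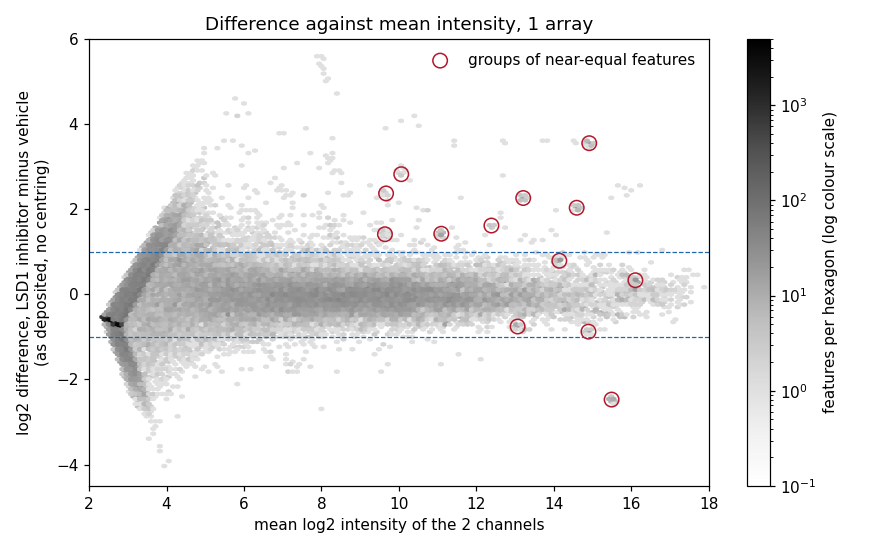
Log2 difference between LSD1 inhibitor and vehicle as deposited (y axis) against the mean log2 intensity of the 2 channels (x axis) on 1 array; grey hexagons count features on a log colour scale, circles mark the 13 groups of near-equal features and dashed lines the 2-fold threshold. The circled groups lie between -2.47 and 3.55, and the wedge at low intensity holds the features in the floor bands.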

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

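The number of features at least 2-fold higher was 3351 and of those lower 201 as planned, and higher features outnumbered lower ones under each of the 8 planned and 6 added alternatives, but the counts moved by over 1.5 times under most. Higher and lower features numbered 2178 and 441 without centring, 1717 and 746 with loess, 1614 and 858 with quantile normalization, 5461 and 2161 with no filter, 824 and 53 with a filter at the 70th percentile, 519 and 68 with an offset of 50, 7858 and 758 at 1.5-fold, and 1468 and 52 at 3-fold. Under alternatives chosen after seeing the data they numbered 1220 and 633 above the floor band in both channels without centring, 1131 and 71 at a mean log2 value of at least 6, 2255 and 416 with centring on features above the floor band, 2250 and 411 with block medians subtracted, 1306 and 456 with loess fitted to and counted over features above the floor band, and 3135 and 166 without the groups of near-equal features. Dropping the centring lowers each difference by 0.28 and a filter changes which features are counted, by construction; for the other moves the cause was not tested. Without centring, all 201 lower features had to remain lower, and the 2178 higher features had to be among the 3351, since each difference fell by 0.28. With loess, all 201 lower features remained lower and 1717 of the 3351 higher features remained higher. Applying loess over all features and the restriction to features above the floor band together turned the split at 2-fold, to 976 higher and 1228 lower. The split also turned at 1.5-fold (2761 and 3485), though not at 4-fold (226 and 83). Of the 24 alternative values of the 4 named features, 23 moved by more than the spread within near-equal groups (SD 0.032): feature 38602 ranged from 4.43 to 5.61, feature 61914 from 4.37 to 5.60, feature 30355 from -4.26 to -1.01 and feature 51581 from -3.20 to -0.79, where the offset of 50 ended its 2-fold call. No paired analysis was possible because each group has 1 sample, and for the same reason no sample could be left out. The alternative that takes a gene's brightest probe and the gene list shifts were not run, since features were not matched to genes. Signal over background limits features with a channel in the floor band and may limit dim ones among the 31423 above it in both.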

Other observations

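The test of the floor band, the loess fitted without floor features, that of the near-equal groups as a source of the imbalance and that of repeated printing were chosen after the results they concern had been seen.

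Over all features, the excess of higher over lower features may be partly technical. After subtracting block medians of the array surface, 68.2% of the 2-fold changes above the floor band in both channels were higher (62.0% to 77.3% in 8 bands of rows), which argues against a surface trend as the whole source. Without centring, the same features gave 65.8% higher (58.8% in the lowest band), against 89.5% with it, so the centring, on a median set by floor values, added to the excess. For these features as a whole the test does not decide, because the bands straddle its bound of 60%. At a mean log2 value of at least 6, outside the near-equal groups, 80.4% were higher without centring (69.8% to 90.1% in the 8 bands). For those features this argues against the centring as the whole source. A smooth dye trend with intensity stays open: loess fitted to all features left 44.3% higher (40.1% to 55.8%), but loess fitted without the features in the floor bands left 74.1% higher (66.1% to 83.9%).

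At a mean log2 value of at least 6, the excess at 2-fold is harder to ascribe to scaling. At 1.5-fold the excess was smaller, with 1662 features higher and 1209 lower without centring. After loess fitted to all features, 82.7% of 2-fold changes were higher (73.8% to 91.2% in the 8 bands). This argues against a smooth dye trend in the deposited values as the whole source. No loess fitted without floor features was counted for this set. The earlier dye normalization is not given, so a trend that it removed or added could not be seen. Leaving out the near-equal groups gave 80.4% without centring (69.8% to 90.1%), which argues against those groups as the whole source. Repeated or control spots that the search did not group stayed in this count, so it cannot decide on them. The search needed at least 6 features within 0.1, and features 38602 and 61914, for example, lay in no group. Dye effects of single features and the treatment cannot be told apart, since 0 arrays had the dyes swapped and each treatment had its own dye. An effect of the treatment therefore stays open and untested, and which features are genes and which are controls was not analysed here.

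The larger groups of near-equal features may each be 1 probe printed at many places. In 10 of the 13, the median distance from a member to its nearest fellow member lay within the central 95% of 10000 random sets of the same size, and in the other 3 it was longer, which argues against a local blemish. The 9 groups of over 20 features differed in size by only 1.11 times (35 to 39 features), as repeated printing would give, but that limit was set after the sizes were seen, and the other groups had 16, 10, 5 and 5 features, for which the explanation stays open. Whether the groups detect cell transcripts or added control RNA stays open, and no biological explanation was tested. Their SDs of the log2 difference, from 0.027 to 0.072, are held low by the search radius.

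The 10 features with the largest increases spanned rows 79 to 378 and columns 2 to 126 of the inferred layout. Their median nearest distance was 17.5 positions, which was as short or shorter in 0.67% of random sets of 10. They thus lay closer together than most random sets, unlike the groups above, and a local blemish stays open for them.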
